A study of Solanum lycopersicum with 13 samples.

How the data were processed

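The data are mRNA sequencing of mature tomato leaves from 3 groups of 2 libraries each. The control, wtR1, is the progeny of a wild-type plant regenerated through tissue culture. The mutant groups are 2 T1 progeny, slmet1-1-T1-A and, separately, slmet1-1-T1-B, of a line mutated in the DNA methyltransferase gene SlMET1. The labels put the RNA in the same leaf material as DNA taken for bisulfite sequencing. The 7 bisulfite samples were not analysed here, so no statement on DNA methylation is made.

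The authors deposited FPKM (fragments per kilobase of gene model scaled to the mapped fragments) for 34723 genes, with 1 column per library. Per the submitters' processing notes, TopHat2, Cufflinks and Cuffdiff were used; their order, versions, genome build and annotation are not given in the sources used here. The FPKM of a library summed to between 1038811 and 1345853, so the columns are not TPM. All 6 columns matched 1 sample each. No count of fragments can be read from FPKM, so the absolute depth is unknown. The steps between values of weakly detected genes gave relative depths, against wtR1 replicate 1, of 1.14 for wtR1 replicate 2, 1.17 and 1.06 for slmet1-1-T1-A replicates 1 and 2, and 0.743 and 1.10 for slmet1-1-T1-B replicates 1 and 2. Values in slmet1-1-T1-B replicate 1 therefore rest on the fewest fragments. An exact 0 in such a table can be a failed estimate, and a gene is then only said to be listed at 0.

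As FPKM are not counts, no count model was used. Genes with a mean of at least 0.5 FPKM over the 6 libraries (20611 genes) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. There was 1 fit over the 3 groups, with 3 residual degrees of freedom, moderated variances that followed the mean level, and Benjamini-Hochberg adjustment. A gene was called higher or lower, or said to have risen or fallen, at an adjusted p under 0.05 and a log2 difference of at least 1 in size. Every log2 difference is on the log2(FPKM + 1) scale, which understates changes of low genes; folds are ratios of mean FPKM. On simulated values for slmet1-1-T1-A against wtR1, over 20611 genes, changes were added to genes with a mean of at least 1 on the log2(FPKM + 1) scale. The fit called 45 of 50 genes changed 2.5-fold on that scale, 48 of 50 changed 4-fold and 49 of 50 changed 8-fold, with 1 other gene called. These rates do not hold for low genes with the same ratios of FPKM. Changes of 1.5-fold lie under the minimum size and cannot be called; 37 of 50 passed the adjusted p alone. Nothing in the labels says that the 2 libraries of a group came from separate plants. The p-values thus measure only the spread between these libraries, which may be technical, and each mutant group may stand for a single plant.

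Gene lists were fixed before the data were examined, and 17 of 22 could be used; the other 5 were defined by gene descriptions, which the table does not hold. The 12 lists with at least 3 tested genes were tested with camera at a correlation of 0.01, and again with an estimated correlation and with fry. Neither the table nor the RefSeq gene table for assembly SLM_r2.1 pairs the locus identifiers with symbols, and 0 of its rows held such an identifier. Symbols therefore come from pairs of symbol and identifier recalled from published nomenclature and written down before the data were examined. Their only check was position: of 135 identifiers, 89 had a symbol in RefSeq. RefSeq placed 81 of these on the same chromosome at a similar relative position (within 0.05 of its length in genes), and 8 elsewhere, while 0.76% of random pairs were placed alike. The tolerance was set after the positions were seen: it was widened because SlMET1 and MYB12 fell outside a narrower one. Only symbols placed alike are named, and a symbol remains an assignment by memory and position, not by a matching table. The lists also hold the 46 identifiers without a symbol in RefSeq and the 8 placed elsewhere. List counts and list tests thus rest partly on unchecked identifiers, and for the clock genes wholly.

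Named genes follow a rule written beforehand: at most 4 per list and comparison (called members with the greatest change, then the most abundant), SlMET1, and at most 2 identifiers that rose and 2 that fell per comparison. A gene named in 1 comparison may also be given in others, but not always. Genes named outside the rule are said to be. Restricting names to symbols placed alike was a later choice. Alternatives written beforehand were other pseudocounts, filters, scalings and thresholds, fits of only 2 groups, other variance models, a replicate block, each library left out, and other list tests. Chosen after seeing the data were fits without chromosome 2, without genes at 0 in both libraries of a group, without 74 genes at least 8-fold higher in slmet1-1-T1-B replicate 1 than in replicate 2 (and at least 20 FPKM in the higher library), without the 84 that differed so in either direction, and lists without symbols placed elsewhere. The segments of chromosome 2 were also defined after seeing the data, by a fit of 2 breakpoints to genes with a mean of at least 5 FPKM, in the order of their identifiers; the step was tested on simulated values. Segment errors are bootstrap errors over genes (2000 resamples), and genes are not independent replicates. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used. Gene length and GC content were not analysed here.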

Results

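Leaf transcriptomes were compared between regenerated wild-type tomato (wtR1) and 2 T1 progeny of a mutant in SlMET1, the tomato orthologue of the maintenance DNA methyltransferase MET1. Each group had 2 libraries, and expression was given as FPKM. Between 23052 and 23613 of 34723 genes had a value above 0 in a library. Replicate values of genes with a mean of at least 0.5 FPKM correlated across genes at 0.982 in wtR1, 0.987 in slmet1-1-T1-A and 0.972 in slmet1-1-T1-B. In slmet1-1-T1-B replicate 1, 74 genes that were at least 8-fold lower in replicate 2 made up 22.6% of the summed FPKM; 10 genes differed as much in the other direction.

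The first question was how the mutated gene itself and the other DNA methylation genes were expressed. SlMET1 (Solyc11g030600) was at 19.1 ± 0.25 FPKM in wtR1, 10.8 ± 0.0036 in slmet1-1-T1-A and 7.61 ± 0.115 in slmet1-1-T1-B (SD, n = 2 each). It fell in slmet1-1-T1-B, 2.52-fold (log2 difference −1.23, SE 0.0355, limma adjusted p = 8.63e-06). In slmet1-1-T1-A it was 1.78-fold lower (−0.78, adjusted p = 8.18e-05), short of the minimum size. The labels give no mutated site, and the mRNA level alone does not check the genotype. The chromomethylase genes SlCMT2 and SlCMT3, which act on non-CG methylation, fell in slmet1-1-T1-B as well, from 18.9 ± 0.577 to 7.46 ± 0.16 FPKM and from 6.31 ± 0.224 to 1.02 ± 0.134 FPKM. In slmet1-1-T1-A they were at 10.4 ± 0.27 and 3.55 ± 0.016 FPKM. The demethylase genes SlDML1 and SlDML2 differed from wtR1 by 0.14 and −0.13 on the log2 scale in slmet1-1-T1-A. In slmet1-1-T1-B they differed by 0.27 and −0.41, also under the minimum size. SlDRM5 was at 32.0 ± 0.464 FPKM in slmet1-1-T1-A against 20.3 ± 0.274 in wtR1; it lies in the part of chromosome 2 that was higher in this group. Of the 17 methylation genes, 0 passed in slmet1-1-T1-A, while 0 rose and 4 fell in slmet1-1-T1-B, with the same counts adjusted over the list alone. The camera test placed the list lower in slmet1-1-T1-B (adjusted p = 0.00442; adjusted p = 0.411 with an estimated correlation). SlMET1 itself is on this list and among the 4 that fell, and the list was not tested without it.

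**Figure D1:**
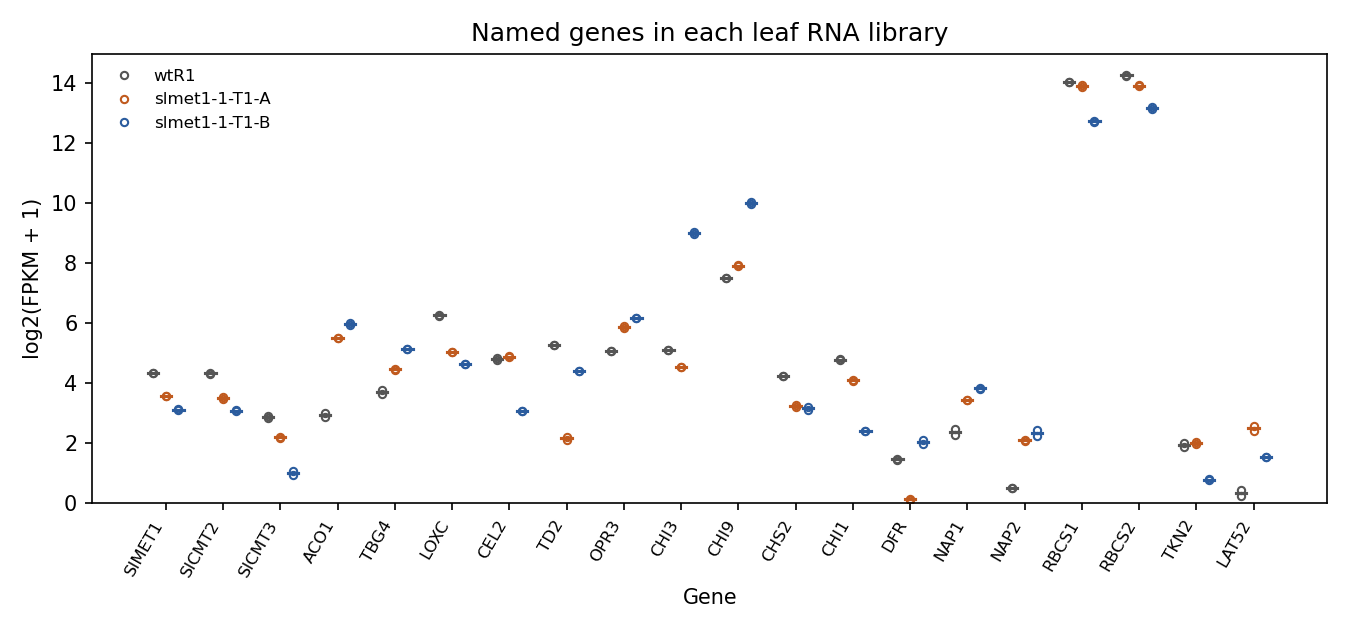
Expression of 20 genes as log2(FPKM + 1) in each library; open circles are the 2 libraries of a group and the short bar is their mean, with groups told apart by colour. The replicate points lie close together, and SlMET1 is lower in both mutant groups than in wtR1.

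In slmet1-1-T1-A, the ethylene-forming enzyme gene ACO1 rose 6.62-fold, from 6.69 ± 0.498 to 44.3 ± 0.362 FPKM (log2 difference 2.56, SE 0.0508, limma adjusted p = 9.67e-06). The wound-induced threonine deaminase gene TD2 fell 10.7-fold, from 37.1 ± 0.0231 to 3.47 ± 0.23 FPKM. Of the anthocyanin genes, the synthesis gene DFR fell from 1.75 ± 0.0468 to 0.0927 ± 0.0161 FPKM, and the regulator AN2 from 5.84 ± 0.946 to 1.98 ± 0.502 FPKM. The senescence-related NAC genes NAP1 and NAP2 rose, to 9.75 ± 0.0773 and 3.28 ± 0.0692 FPKM from 4.15 ± 0.503 and 0.427 ± 0.00193 FPKM. The difference of NAP1 was just under the minimum size without wtR1 replicate 2 (0.966), with quantile normalization (0.957) and with median centring (0.915). In total, 867 genes were higher and 200 lower than in wtR1.

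Of 11 flavonoid and anthocyanin genes, 0 rose and 2 fell in slmet1-1-T1-A, and the list was lower as a whole (median log2 difference −0.71, camera adjusted p = 2.9e-05; adjusted p = 0.19 with an estimated correlation). CHI1, chalcone isomerase, was at 16.0 ± 0.389 FPKM against 26.3 ± 0.33 in wtR1 (−0.69). The chalcone synthase genes CHS1 and CHS2, named here after their values were seen, differed by −0.997 and −0.999. They passed the minimum size under median centring (−1.148 and −1.149), quantile normalization and smaller pseudocounts, and without wtR1 replicate 2 (−1.027 and −1.002) or slmet1-1-T1-A replicate 1 (−1.001 and −1.047). Of 11 jasmonate and wound genes, 0 rose and 4 fell (median −0.88, adjusted p = 0.0793). Among the 4, only TD2 has a symbol placed alike in RefSeq. Of 6 genes of salicylate and pathogenesis-related defence, 3 rose and 0 fell (adjusted p = 0.0811; adjusted p = 0.365 with an estimated correlation, but 0.0318 with median centring and 0.0057 without chromosome 2, which removes CHI3, the 1 member with a negative difference, −0.56); CHI9, a chitinase gene, was at 239.5 ± 0.854 FPKM against 179.8 ± 0.956. None of the 3 salicylate and pathogenesis-related genes that rose has a symbol in RefSeq. Of 14 ripening genes, ACO1 rose and the lipoxygenase gene LOXC fell, from 75.0 ± 0.367 to 32.0 ± 0.183 FPKM (adjusted p of the list = 0.914). Of 8 photosynthesis genes, only RBCS3, listed at 0 in wtR1, passed (camera lower, adjusted p = 0.0793; adjusted p = 0.647 with an estimated correlation); the list was called lower without slmet1-1-T1-B replicate 1 (0.0459) or without genes at 0 in a group (0.00747). RBCS1 was at 15157 ± 570 FPKM in slmet1-1-T1-A. Of 3 senescence genes, NAP1 and NAP2 rose (adjusted p = 0.1), and SGR1 was at 12.2 ± 1.15 against 10.6 ± 0.0489 FPKM. No member passed among 5 carotenoid genes (adjusted p = 0.0793), 9 floral regulators (0.367), 7 clock genes (0.556), 9 reference genes (0.914), 3 trichome genes (0.695), 2 auxin genes, 2 heat shock genes, 1 DELLA gene and 1 meristem gene. With a mean of at least 5 FPKM, which drops the 1 carotenoid gene with a positive difference, camera called that list lower (adjusted p = 0.0256). At the main filter an estimated correlation gave 0.365. The pollen gene LAT52 rose from 0.260 ± 0.119 to 4.62 ± 0.401 FPKM. In each of these lists the counts adjusted over the list alone were the same. Of genes known only by identifier, Solyc07g007720 rose from 1.45 ± 0.15 to 111.8 ± 7.32 FPKM and Solyc03g098790 fell from 2038 ± 36.8 to 48.1 ± 0.224 FPKM. Solyc12g007080 was at 36.1 and 14.2 FPKM in the wtR1 libraries and listed at 0 in both libraries of slmet1-1-T1-A.

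In slmet1-1-T1-B, genes of pathogen defence rose: the chitinase genes CHI3, 15.3-fold from 33.2 ± 0.269 to 508.9 ± 17.2 FPKM (log2 difference 3.90, SE 0.0304, limma adjusted p = 1.38e-06), and CHI9, 5.67-fold to 1020 ± 34 FPKM. Solyc00g174340, entered in the same list as a pathogenesis-related gene, rose from 42.3 ± 3.3 to 2364 ± 8.36 FPKM. ACO1 rose 9.17-fold to 61.4 ± 1.41 FPKM. The small-subunit Rubisco genes RBCS1 and RBCS2 fell, from 16510 ± 104 to 6689 ± 172 FPKM and from 19326 ± 145 to 9058 ± 294 FPKM. A further listed gene of this kind, RBCS3, was listed at 0 in wtR1 and at 23911 ± 304 FPKM in slmet1-1-T1-B. A fall of the small-subunit genes as a set is therefore not shown. Whether the estimate for RBCS3 affected those for RBCS1 and RBCS2 was not tested. In total, 1753 genes were higher and 1072 lower than in wtR1 (661 lower among genes with a mean of at least 5 FPKM).

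Of 6 genes of salicylate and pathogenesis-related defence, 5 rose and 0 fell in slmet1-1-T1-B (median log2 difference 3.90, camera adjusted p = 0.00442; adjusted p = 0.367 with an estimated correlation). Among the 5, only CHI3 and CHI9 have a symbol placed alike in RefSeq. CHI3 lies in the part of chromosome 2 that was higher in this group by a median of 0.66. Of 8 photosynthesis genes, 3 fell, RBCS1 and RBCS2 among them. RBCS3 (Solyc02g085950) was listed at 0 in both wtR1 libraries and at 23697 and 24126 FPKM in slmet1-1-T1-B, so it has no fold and its call may be void. The median of that list was −0.66 and its mean 1.13, which has the opposite sign because of RBCS3 (camera lower, adjusted p = 0.0107; adjusted p = 0.517 with an estimated correlation). Under quantile normalization the log2 difference of RBCS2 grew from −1.09 (SE 0.0407) to −1.41 (SE 0.594), and the larger SE ended its call (adjusted p = 0.0867). That scaling also ended the call of the list (0.511), which was also lost under median centring (0.103) and without symbols placed elsewhere (0.0583). Of 11 flavonoid genes, 0 rose and 3 fell (adjusted p = 0.0159; adjusted p = 0.367 with an estimated correlation, 0.0901 with quantile normalization and 0.0886 with median centring), with CHI1 going from 26.3 ± 0.33 to 4.28 ± 0.0148 FPKM and CHS2 from 17.8 ± 0.0497 to 7.92 ± 0.394 FPKM. Of 11 jasmonate and wound genes, 4 fell and 1 rose (adjusted p = 0.0987); the riser was OPR3, an enzyme of jasmonate synthesis, at 70.3 ± 0.0692 against 32.6 ± 0.181 FPKM, named after its value was seen. Its log2 difference of 1.08 missed the minimum size under median centring (0.874) and quantile normalization (0.914). None of the 4 jasmonate and wound genes that fell has a symbol in RefSeq.

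Of 14 ripening genes, 2 rose and 2 fell in slmet1-1-T1-B (adjusted p = 0.711). The beta-galactosidase gene TBG4 rose from 12.04 ± 0.852 to 33.98 ± 0.345 FPKM, and the endoglucanase gene CEL2 fell from 27.0 ± 1.15 to 7.35 ± 0.0351 FPKM. Of 9 floral regulators, 1 rose and 1 fell (adjusted p = 0.949); the MADS-box gene TM6, on the middle of chromosome 2, rose from 10.2 ± 0.436 to 23.4 ± 0.0231 FPKM. Its log2 difference was 1.12, and 0.46 after the median of the middle was subtracted, under the minimum size, which it also missed under median centring (0.913) and quantile normalization (0.923). NAP1 and NAP2 rose, to 13.1 ± 0.288 and 4.07 ± 0.492 FPKM (adjusted p of the senescence list = 0.141). The meristem gene TKN2 fell from 2.83 ± 0.197 to 0.710 ± 0.0286 FPKM, and LAT52 rose to 1.90 ± 0.0206 FPKM, but missed the minimum size under median centring (0.994). No member passed among the carotenoid (adjusted p = 0.0987), clock (0.967), reference (0.624), trichome (0.6), auxin, heat shock and DELLA genes. With a mean of at least 5 FPKM, camera called the carotenoid list lower (adjusted p = 0.0216), again without its 1 gene with a positive difference. At the main filter an estimated correlation gave 0.411. The reference genes GAPDH and ACT differed by −0.06 and 0.68. Counts adjusted over the list alone were again the same. Of genes known only by identifier, Solyc09g062970 fell from 147.0 ± 14.8 to 3.51 ± 0.97 FPKM and Solyc07g006380 from 92.4 ± 3.87 FPKM to 0 and 0.06 FPKM in the 2 libraries.

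The share of calls that were higher depended on scaling. As deposited, 81.3% of the calls in slmet1-1-T1-A and 62.1% in slmet1-1-T1-B were higher. With each library centred on the median of its genes with a mean of at least 5 FPKM, these shares were 69.0% and 41.0%. In slmet1-1-T1-B more genes were then lower (1718) than higher. With quantile normalization the shares were 70.2% and 51.3%. The median log2 difference of all tested genes was 0.08 and 0.12 as deposited. Centring moved it by −0.15 and −0.21, to negative values of −0.07 and −0.09, and quantile normalization gave −0.05 and −0.02. The majority of lower calls in slmet1-1-T1-B was thus seen only with centring, which moved this median furthest. No named gene that was called changed direction under either scaling. Centring shifts every gene of a library alike, by too little to reverse a log2 difference of at least 1, so for centring this was fixed in advance. With no minimum size, 7040 genes were higher and 3541 lower in slmet1-1-T1-A, and 8834 and 5769 in slmet1-1-T1-B.

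Both progeny had 480 genes called higher and 118 called lower than wtR1. With a pseudocount of 0.1 these were 773 and 179, and with median centring 182 were lower. Independent lists of these sizes would share 73.7 and 10.4 genes, and simulated groups with no change shared 0.02 and 0.01 on average over 100 simulations. Those simulated comparisons had only 0.17 and 0.11 calls on average, so their overlap could only lie near 0. The correlation of the log2 differences across genes was 0.586, inside the range of those simulations (mean 0.499, highest 0.595). Outside that range were their covariance, 0.24 (mean 0.02, highest 0.031), and the share of genes with the same sign, 76.1% (mean 66.6%, highest 67.5%). Both comparisons used the same 2 wtR1 libraries. The simulated comparisons shared a control group too, but their noise was only the spread between libraries of a group. A difference of the wtR1 material beyond that spread was not simulated, and part of the excess may come from it. ACO1, LOXC, NAP1, NAP2 and LAT52 were called in the same direction in both progeny, and 7 genes were called in opposite directions.

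Directly compared, 945 genes were higher and 736 lower in slmet1-1-T1-A than in slmet1-1-T1-B; the higher count was 1496 with a pseudocount of 0.1 and 595 with a mean of at least 5 FPKM. CHI3, CHI9, TD2, DFR and AN2 were lower in slmet1-1-T1-A, and CHI1, CEL2, RBCS1, TKN2 and SlCMT3 higher. RBCS1 lies in an end of chromosome 2, where the median difference between the progeny was 0.53, and less that median its difference was 0.65, under the minimum size. CHI3, DFR and TKN2 lie in the middle, where the median was −0.56, and less that median differed by −3.90, −1.35 and 1.79. By list, 5 of 6 genes of salicylate and pathogenesis-related defence were lower in slmet1-1-T1-A (median log2 difference −2.82, camera adjusted p = 0.00495; adjusted p = 0.499 with an estimated correlation). Of 8 photosynthesis genes, 2 were higher and 6 did not pass. The 2 were RBCS1 and a gene whose symbol RefSeq placed elsewhere. For this list camera gave higher values (median 0.56, adjusted p = 0.00368). Its adjusted p was 0.699 with an estimated correlation and 0.262 with quantile normalization. Of these 8 genes, 7 lie on chromosome 2, RBCS1 in an end and 6 in the middle. Less the median of the middle, those 6 differed by 0.655 to 1.565, against 0.099 to 1.009 before. The shift of the middle thus worked against the list being higher. The upper value of each range belongs to the called gene whose symbol RefSeq placed elsewhere. Of 17 methylation genes, 1 was higher and 16 did not pass, and camera placed the list higher (median 0.28, adjusted p = 0.0263; adjusted p = 0.699 with an estimated correlation). The methylation list was no longer called without slmet1-1-T1-B replicate 2 (adjusted p = 0.0526), without chromosome 2 (0.297) or with a mean of at least 5 FPKM (0.0814).

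Along chromosome 2, whole segments differed between the groups. In slmet1-1-T1-A, the 597 genes before Solyc02g067460 and from Solyc02g090110 on had a median log2 difference from wtR1 of 0.60 ± 0.010 (bootstrap SE), against 0.08 ± 0.012 for the 1031 genes between. In slmet1-1-T1-B, the 1028 genes from Solyc02g067390 to Solyc02g090010 had a median of 0.67 ± 0.018, against 0.08 ± 0.021 for the 600 genes outside. The breakpoints, found separately in each group, thus fell at nearby genes. Genes of chromosomes 1 and 3 to 12 had medians of 0.08 and 0.13. Each pairing of a mutant with a wtR1 library gave an excess over those chromosomes of 0.53 for the ends in slmet1-1-T1-A and of 0.53 to 0.55 for the middle in slmet1-1-T1-B. Chromosome 2 held 145 of the 867 genes higher in slmet1-1-T1-A and 376 of the 1753 higher in slmet1-1-T1-B, with 2198 of the 20611 tested genes.

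**Figure D2:**
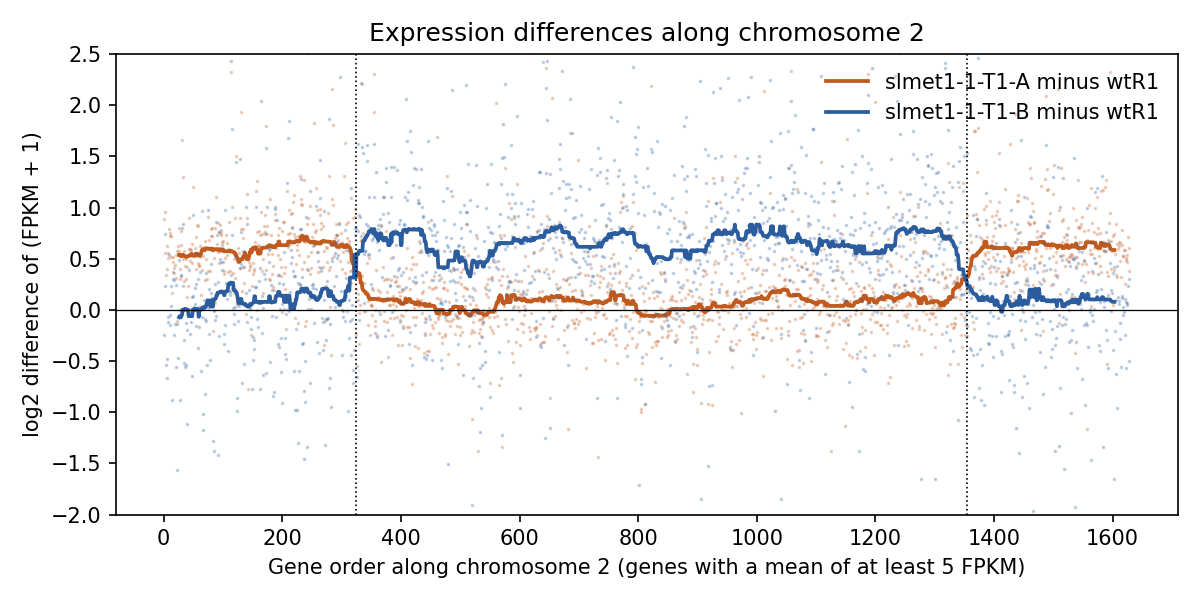
Log2 difference of (FPKM + 1) from wtR1 for 1628 genes in order along chromosome 2; points are genes, lines are running medians over 51 genes and dotted lines are the breakpoints found in slmet1-1-T1-A; the few points beyond the axis limits are not drawn. The ends are raised in slmet1-1-T1-A and the middle in slmet1-1-T1-B.

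Genes at or near 0 FPKM in wtR1 were examined because loss of methylation can release silent genes. With under 0.1 FPKM in both wtR1 libraries and at least 1 FPKM in all 4 mutant libraries there were 18 genes, of 12418 low in wtR1; the reverse held for 5 genes of 18693 present in wtR1. Of the 18, 15 were listed at exactly 0 in both wtR1 libraries, RBCS3 among them, so an absence of transcript is not shown. Solyc12g100260 was listed at 0 in wtR1 and at 44.5 to 54.4 FPKM in the mutant libraries. In slmet1-1-T1-A alone the counts were 45 and 9, and in slmet1-1-T1-B 52 and 28, which became 34 and 17 with exactly 0 FPKM as the limit and 92 and 66 with under 0.5 and at least 2 FPKM. Low values are close to single fragments. The limits must hold in every library kept, so leaving 1 out can only keep or raise these counts. Without wtR1 replicate 1 or wtR1 replicate 2 the count of 18 became 44 or 41 and the count of 5 became 21 or 29. Without slmet1-1-T1-A replicate 2 the count of 5 became 10. With any 1 library of wtR1 or slmet1-1-T1-A left out, the counts of 45 and 9 became 90 to 97 and 23 to 52. With any 1 library of wtR1 or slmet1-1-T1-B left out, those of 52 and 28 became 104 to 116 and 54 to 74.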

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

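The flags below come from the direct contrast of the 2 progeny; the tests of explanations in this part were all chosen after the results were seen. On the log2 scale, slmet1-1-T1-A minus slmet1-1-T1-B, lower values were found for CHI3 (−4.45), Solyc00g174340 (−2.92), TD2 (−2.24), CHI9 (−2.09), DFR (−1.90), Solyc03g098790 (−1.59) and AN2 (−1.20). Higher values were found for Solyc09g062970 (4.48), Solyc07g006380 (2.98), CEL2 (1.82), CHI1 (1.68), TKN2 (1.23), RBCS1 (1.18) and SlCMT3 (1.18). The limma adjusted p was at most 0.00243 in each, and the libraries of the 2 groups did not overlap. All 1681 genes called in this contrast had no overlap, so this does not set the flagged genes apart. List medians differed by −2.82 for salicylate and pathogenesis-related defence, 0.56 for photosynthesis and 0.28 for methylation genes. With an estimated correlation these 3 lists were not called (adjusted p = 0.499, 0.699 and 0.699), nor was photosynthesis with quantile normalization (0.262) or methylation without chromosome 2 (0.297). RBCS1 lies in an end of chromosome 2, and less the median of the ends its difference was 0.65. With 1 T1 group on each side, a difference between the progeny and a difference between 2 plants or leaf samples were not separated by the design.

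The raised segments of chromosome 2 have 3 explanations that were tested, cutting each group's segment at the breakpoints found in the other. Release of weakly expressed genes would spare abundant ones, but the most abundant segment genes (200 of 600 and 344 of 1031) had an excess of 0.549 ± 0.017 (ends, slmet1-1-T1-A) and 0.653 ± 0.031 (middle, slmet1-1-T1-B). Abundance was the mean over all 6 libraries, mutant ones included, so the choice of abundant genes leaned toward raised ones. Runs of neighbours on other chromosomes reached at most 0.111 and 0.159, against 0.602 and 0.662. For the middle such a run took nearly all of some chromosomes, and all of chromosomes 10 and 12 (1006 and 995 genes), which are shorter. The ends are 2 separate stretches, but were set against single runs. This comparison had little room for another outcome and does not exclude chance. It shows only that no other chromosome moved as far over so long a stretch. An extra copy of the segment, 3 for 2, predicts about 0.585; genes with a mean of at least 20 FPKM gave 0.533 ± 0.016, below it by more than its error, and 0.608 ± 0.029, those with at least 0.5 FPKM gave 0.497 and 0.482, and a pseudocount of 0.1 gave 0.543 and 0.576. The accepted range was set after excesses of 0.524 and 0.535 at 5 FPKM had been seen, so that test could hardly fail, and an extra copy, which DNA read depth could test, stays open beside regulation of whole segments, which was not tested.

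RBCS3 at 0 in both wtR1 libraries, beside 23697 FPKM or more elsewhere, could be a failed estimate or a true loss, and these cannot be told apart. A failed estimate was predicted to need a rank among the 5 most abundant genes in each mutant library. The lowest rank was 6, so the bound was missed by 1. Only slmet1-1-T1-B replicate 1, where the 10 most abundant genes held 25.92% of the summed FPKM, has room for this rank. In the other mutant libraries these genes held 11.75 to 13.64%, so the miss depends on that library. RBCS1 and RBCS2 were not low in wtR1. The next measured genes on each side went opposite ways in slmet1-1-T1-A (0.301 on average): Solyc02g085940, near the floor, was listed at 0 in wtR1 and at 0.858 FPKM (log2 difference 0.89), while Solyc02g086050 was at 36.2 FPKM in wtR1 and at 29.4 (−0.29). A loss of the transcript is thus not excluded, and FPKM alone do not decide this.

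The 74 genes high in slmet1-1-T1-B replicate 1 summed to 304177 FPKM there and 7222 in replicate 2. A further 10 genes differed as much the other way, listed at 0 in replicate 1 and summing to 1148 FPKM in replicate 2. In the wtR1 and slmet1-1-T1-A libraries these 10 genes summed to 662 to 1215 FPKM, so as a set they were missing only from slmet1-1-T1-B replicate 1. A difference between the genotypes cannot by itself part 2 libraries of 1 genotype, so the gap between 304177 and 7222 FPKM argues against it as the source. Whether such a difference added to the gap is not decided. Of the 4 other libraries, 3 lay above replicate 2, but choosing genes low in replicate 2 makes that outcome likely in advance. The 74 genes also differed between the wtR1 libraries, with a median log2 ratio of 2.215 ± 0.158 (27673 against 2998 FPKM summed), which is consistent with a class of RNA carried over to a different extent in each library. Which class was not tested, as no gene descriptions were used.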

How the results depend on the processing

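Fits without chromosome 2, without genes at 0 in a group, without the 74 genes high in slmet1-1-T1-B replicate 1 or the 84 that differed either way, lists without symbols placed elsewhere, and other filters and a pseudocount of 0.1 for the chromosome 2 segments were chosen after seeing the data; the other alternatives were not. No gene called against wtR1 was called in the opposite direction in any alternative, and no list did with camera; the cause of the changes below was not tested unless it is stated. A pseudocount of 0.1 gave 1496 genes higher in slmet1-1-T1-A than slmet1-1-T1-B, and 773 higher and 179 lower in both progeny. A mean of at least 5 FPKM, which tests fewer genes, gave 661 lower in slmet1-1-T1-B and 595 higher in slmet1-1-T1-A than slmet1-1-T1-B, and adjusted p of 0.0256 and 0.0216 for carotenoid genes in the A and B progeny and of 0.0814 for methylation genes between the progeny. Median centring gave 1718 genes lower in slmet1-1-T1-B and 182 lower in both. With no minimum size, 7040 genes were higher and 3541 lower in slmet1-1-T1-A, 8834 and 5769 in slmet1-1-T1-B, 6173 and 6270 between the progeny, and 5454 and 2755 in both. Quantile normalization gave an adjusted p of 0.0901 for flavonoid genes and 0.511 for photosynthesis genes in slmet1-1-T1-B, and 0.262 for photosynthesis genes between the progeny. Median centring gave 0.0886 and 0.103 for these lists in slmet1-1-T1-B and 0.0318 for salicylate defence genes in slmet1-1-T1-A. Without chromosome 2, salicylate defence genes in slmet1-1-T1-A had 0.0057 and methylation genes between the progeny 0.297, with 721 and 189 genes higher and lower in slmet1-1-T1-A and 1377 and 991 in slmet1-1-T1-B. Without genes at 0 in a group, which removes RBCS3, photosynthesis genes in slmet1-1-T1-A had 0.00747, and without symbols placed elsewhere those in slmet1-1-T1-B had 0.0583. An estimated correlation ended every list call: flavonoid genes in slmet1-1-T1-A (0.19); methylation (0.411), flavonoid (0.367), photosynthesis (0.517) and salicylate defence genes (0.367) in slmet1-1-T1-B; methylation (0.699), photosynthesis (0.699) and salicylate defence genes (0.499) between the progeny. The fry test, which asks whether a list moves and not whether it moves more than other genes, added calls. In slmet1-1-T1-A these were carotenoid (0.00058), methylation (0.0159), floral (0.00145), ripening (0.00211), jasmonate (4.2e-05), senescence (0.000454), reference (0.00145) and salicylate defence genes (0.000198), and in slmet1-1-T1-B carotenoid (0.000174), clock (0.00656), jasmonate (0.000132), senescence (0.000191) and reference genes (0.000278). Between the progeny they were carotenoid (0.00221), clock (0.00615), floral (0.00929), ripening (0.00173), jasmonate (0.00113), senescence (0.0156), trichome (0.0175) and reference genes (0.00331). With fry the direction turned for photosynthesis genes in slmet1-1-T1-A (2.15e-05) and in slmet1-1-T1-B (1.96e-05), floral genes in slmet1-1-T1-B (0.000702) and flavonoid genes between the progeny (0.00119). With 1 library left out, its group keeps 1 sample that is assumed to vary like the others. Genes under 0.1 FPKM in wtR1 and at least 1 in mutant libraries then numbered 21 to 44 in both progeny, 45 to 97 in slmet1-1-T1-A and 52 to 116 in slmet1-1-T1-B, and the reverse 5 to 29, 9 to 52 and 28 to 74. With fewer libraries to meet the limits, such counts can only stay or rise. In slmet1-1-T1-B these counts were 34 and 17 with exactly 0 FPKM as the limit, and 92 and 66 with under 0.5 and at least 2 FPKM. With 1 library left out, photosynthesis genes in slmet1-1-T1-A had an adjusted p of 0.0459 to 0.143 and methylation genes between the progeny 0.016 to 0.0526. With a replicate block, 880 and 201 genes were higher and lower in slmet1-1-T1-A and 1760 and 1074 in slmet1-1-T1-B, and no call of a named gene or list changed. Deviations of same-numbered libraries correlated across genes at 0.034 (wtR1 and slmet1-1-T1-A), 0.397 (wtR1 and slmet1-1-T1-B) and −0.086 (the 2 progeny). Their rank correlations were −0.062, 0.024 and −0.022, and the numbers were not taken as pairs. The 74 genes high in slmet1-1-T1-B replicate 1 were also higher in wtR1 replicate 1 than in wtR1 replicate 2 (27673 against 2998 FPKM summed). Whether these 2 replicate 1 libraries shared a batch was not tested. The unknown depth limits the low values most, in slmet1-1-T1-B replicate 1 above all.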

Other observations

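Among genes of other processes, the auxin-response gene IAA9 was at 120.7 ± 0.588 FPKM in wtR1, 184.8 ± 3.46 in slmet1-1-T1-A and 198.6 ± 7.95 in slmet1-1-T1-B, below the minimum size in both. The gibberellin-response repressor PROCERA was at 114.9 ± 5.03, 134.1 ± 5.58 and 117.1 ± 1.38 FPKM, and the carotenoid gene PDS at 115.0 ± 0.0516, 100.8 ± 1.65 and 87.8 ± 0.704 FPKM. MYC2, a regulator of jasmonate responses chosen after its values were seen, was at 32.7 ± 1.14 FPKM in wtR1, 65.1 ± 3.2 in slmet1-1-T1-A and 36.6 ± 0.119 in slmet1-1-T1-B. It was not called in slmet1-1-T1-A (log2 difference 0.97), but passed the minimum size without wtR1 replicate 1 (1.005) or slmet1-1-T1-A replicate 1 (1.02).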
